A study of Nothobranchius furzeri with 12 samples.

How the data were processed

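RNA was sequenced from tail fins of the turquoise killifish, Nothobranchius furzeri, a short-lived African annual fish. The 12 libraries fall into 4 groups of 3: red tails of the strain MZCS002, yellow tails of the strain GRZ-BELL, and female tails of each strain. Per the labels' protocols, the pigmented part of the tail fin, or the matching part in females, was cut out, RNA was extracted with QIAzol and treated with DNase, and cDNA was primed with oligo-dT. The series' design text states 3 biological replicates per group. Samples were grouped by their titles, with the replicate number taken from the same label.

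The table deposited by the authors holds a signal per transcript: read counts divided by a size factor per library, from DESeq2 per the submitters' processing notes. Those notes also name Trimmomatic, STAR and featureCounts. Versions, the genome build, the strand setting and any filter are not given in the sources used here. Each library's values were whole multiples of its smallest value, so that whole reads could be recovered. In all 12 libraries, 100% of the nonzero values came out whole within 0.01 of a read. The recovered totals ran from 5495553 to 17053983 reads per library, and 3 reads equalled 2.04 to 9.43 normalized units. PCR reads without molecular identifiers are not independent molecules, so floors and intervals given for low genes cover counting error only. All 20788 entries carry a RefSeq transcript identifier. Names came from the RefSeq gene table of assembly NfurGRZ-RIMD1, matched on the accession. It matched 14145 entries (68.0%), of which 10617 had a gene symbol. No build is named for the deposited table, so no coordinates are given. A symbol was shared with another entry by 24 entries, and reads of near-identical copies could be split between entries. No read was found for 534 entries.

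The main test was limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend) on log2(value + 1), over the 15170 entries with a mean value of at least 10. All 12 libraries entered one fit with the group as its only term. Of the tested entries, 8701 had a symbol and 6469 only an identifier. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. For a gene with no read in a group, the lower bound of the fold was computed against 3 reads per library. For 1 to 3 reads the ratio of the groups' mean normalized values is given with a 95% counting interval. The interval was computed from the groups' summed reads, scaled by their summed size factors. It is therefore not centred on the ratio printed before it. The 5 contrasts were red against yellow tail, MZCS002 against GRZ-BELL female, each tail against females of its strain, and the difference between the last pair of contrasts. The test of this difference is called the interaction. Because red tails came from 1 strain and yellow tails from the other, colour could not be separated from strain. A further number in the labels, whose meaning is not given in the sources used here, also went with strain, so a batch it could mark cannot be told apart from strain either. The labels do not say that the fish with coloured tails were males. Each tail-against-female contrast set coloured tails against females only, so colour could not be separated from sex there either.

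Lists of genes were tested with camera (limma) at a preset correlation of 0.01, two-sided, and adjusted over 90 pairs of list and contrast. Of 19 lists, 18 were tested: melanin and melanosome, pteridine and xanthophore, carotenoid uptake and handling, guanine and iridophore, neural crest and pigment progenitor, sex steroid and sex determination, thyroid hormone axis, fin ray bone and matrix, epidermis, muscle, immune cells, interferon response, blood, nerve and glia, vessel, cell cycle, immediate early and heat shock, and cytosolic ribosomal proteins. The list of mitochondrially encoded genes had 0 members in the table. The symbol pattern for ribosomal proteins also took in 7 genes that do not encode them, such as S6 kinases. The samples' groups, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule named, per contrast, the 8 called genes with a symbol and the largest increase and the 8 with the largest decrease among those whose groups did not overlap (no such condition for the interaction). It also took the called members of each list with the smallest p (up to 8 for the pigment lists, 4 for the others) and a fixed set of pigment and sex hormone genes. Of that set, scarb1, bco2, slc45a2, sox10, gdf6 and esr1 matched no entry.

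The fit was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by folds of 2, 4 or 16. At these folds it recovered 5.88%, 59.1% and 95.5% of the genes for red against yellow tail (15063 genes tested), and 4.41%, 65.2% and 98.5% for female against female (15069 genes). For red tail against female it recovered 2.94%, 48.5% and 97.0% (15062 genes), and for yellow tail against female 2.94%, 65.2% and 95.2% (15074 genes). For the interaction it recovered 0%, 21.2% and 86.2% (15045 genes). These shares depend on the mix of folds: an earlier simulation without the largest fold recovered no interaction gene. Unchanged genes called numbered 2 to 7 per contrast. A planted list reached an adjusted p of 4.7e-14 with camera, and 0 of 50 random lists were called. The simulated genes were drawn independently of each other. The list simulation therefore cannot show how often camera calls lists of correlated genes by mistake.

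Alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, quantile normalization, scaling to equal totals, robust eBayes, fits on only the groups of a contrast, the replicate number as a block, and a required log2 change of at least 1. Further alternatives were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and each library of a contrast left out in turn. When the recovered reads were tested, edgeR called 1194 genes for red against yellow tail, 283 for female against female, 696 for red tail against female, 300 for yellow tail against female and 33 for the interaction. Replicates of a group were compared by chi-square on their reads. Every pair differed by far more than sampling noise (49.8 to 167 per degree of freedom), so no library was counted as a repeat of another. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.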

Results

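Tail fin RNA of the turquoise killifish was compared between red tails (strain MZCS002), yellow tails (strain GRZ-BELL) and the matching fin region of females of each strain, with 3 libraries per group. Recovered reads came to 13335150, 15282300 and 16968999 in the red tails and 16704074, 5495553 and 17053983 in the MZCS002 females. They came to 13259410, 13496657 and 10463861 in the yellow tails and 11666531, 13516219 and 16113931 in the GRZ-BELL females. MZCS002 female 2 stood apart: its size factor was 0.318, it had 16400 genes with a read against 17644 to 18667 in the other libraries, and its mean correlation with its own group was 0.847 against 0.895 to 0.957. The first 3 principal components held 29.3%, 22.9% and 16.1% of the variance. The design sets coloured tails against the matching region in females of the same strain, and red tails against yellow ones.

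Red tails carried far more transcripts of pigment cell genes than tails of MZCS002 females. The pteridine gene gch2, a GTP cyclohydrolase active in yellow and orange pigment cells (xanthophores), reached 54884 ± 29798 normalized reads against 223 ± 149 (SD, n = 3 each), a log2 change of 8.03 ± 1.08 (SE). The melanin enzyme gene tyr (tyrosinase) was at 2551 ± 871 against 73.6 ± 22.2, and csf1ra, which encodes a receptor that xanthophores need, was at 2845 ± 424 against 262 ± 122. The gene with the largest fitted increase was apoda.1, of the apolipoprotein D family, at 2841 ± 800 against 1.35 ± 1.62. Its females held 2 reads in all, and the ratio of means was 2109 (95% counting interval from summed reads 1148 to 34255). The transcription factor gene pax3a was at 958 ± 69.2 in red tails and had 1 read in the 3 female libraries, a ratio of 4228 (497 to 109478). In limma, the Benjamini-Hochberg adjusted p was 0.0012 for gch2, 6.3e-05 for tyr, 8.1e-05 for csf1ra, 2.8e-05 for apoda.1 and 6.2e-05 for pax3a. The 3 red libraries lay above the 3 female ones for each of these genes.

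Of 19 melanin and melanosome genes, 9 rose in red tails and none fell, while 15 rose adjusted over the list alone. Besides tyr, these were mlana (log2 change 3.33 ± 0.31), trpm1b, an ion channel gene of melanocytes (3.32 ± 0.28), the melanosome traffic genes rab38b (4.51 ± 0.56) and rab32a (1.64 ± 0.25), tyrp1b (2.14 ± 0.37), tspan10 (4.48 ± 0.38), tspan36 (3.50 ± 0.52) and mitfa. Of 19 guanine and iridophore genes, 5 rose (11 adjusted over the list alone). They were the purine nucleoside phosphorylase genes pnp4a (5.76 ± 0.68) and pnp5a (6.04 ± 0.58), fhl2a (7.75 ± 0.76), the transcription factor gene tfec (2.39 ± 0.32) and atic (1.38 ± 0.28). Of 14 pteridine and xanthophore genes, 4 rose (6 higher and 1 lower adjusted over the list alone): gch2, csf1ra, pax7a (2.16 ± 0.33) and xdh (3.30 ± 0.61). Camera gave adjusted p = 8.3e-14 for the melanin list, 1.1e-07 for the guanine list and 0.023 for the pteridine list. With an estimated correlation the adjusted p was 0.26, 0.36 and 0.48, so no call held. Without MZCS002 female 2 the pteridine list had an adjusted p of 0.097. The genes mitfa (2.48 ± 0.57) and xdh lost their calls without red 1 (limma), as they did without red 2, and mitfa also without MZCS002 female 1. The highest limma adjusted p was 0.15 for mitfa and 0.062 for xdh. The call of atic was lost without red 2 or MZCS002 female 3, with a highest adjusted p of 0.098 in limma.

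Outside the pigment lists, tmem130, a gene of a transmembrane protein, was at 106217 ± 53382 in red tails and 945 ± 565 in MZCS002 females (log2 change 6.88 ± 0.61). Other large increases were in prtfdc1a (7.41 ± 0.70), zgc:77375 (7.09 ± 0.68), gpnmb, whose product is found in pigment cells and macrophages (6.74 ± 0.58), and the phosphatase gene dusp2 (4.72 ± 0.43). The caveolin gene cav1 fell, from 1035 ± 245 in females to 167 ± 53.6 (log2 change -2.66 ± 0.31, limma adjusted p = 3.6e-04). Cytosolic ribosomal protein genes fell: 25 of 73 were lower and 1 higher (56 and 2 adjusted over the list alone), with a median log2 change of -1.54 (-0.91 under quantile normalization). Examples were rpl13a (-2.12 ± 0.37) and rpl13 (-2.03 ± 0.37). Camera gave the list adjusted p = 7.3e-21, and adjusted p = 0.65 with an estimated correlation. The call of rpl13 was lost without red 2 (limma adjusted p = 0.059). In a fit on only the 2 groups compared, limma called 0 of the 73 (54 at an unadjusted p under 0.05), while on all groups edgeR called 29 and DESeq2 56. The list's median per library was -1.40, -0.76 and -0.17 in red tails and 0.53, 1.34 and 0.20 in MZCS002 females, the highest value being that of the low-depth library. The androgen receptor gene ar was at 967 ± 152 against 437 ± 149 (log2 change 1.19 ± 0.29, limma adjusted p = 0.041). Its call was lost when any of red 1, 2 or 3 or MZCS002 females 1 or 3 was left out, with a highest limma adjusted p of 0.17. The carotenoid droplet gene plin6 rose (3.67 ± 0.69) and the lipase gene lpla fell (-1.87 ± 0.35), the calls by limma among 13 carotenoid genes (DESeq2 made 3). Both were lost without red 2 (limma adjusted p = 0.064 each).

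In all, limma called 687 genes at a Benjamini-Hochberg adjusted p under 0.05, 411 higher and 276 lower in red tails. All 687 had groups that did not overlap, as had 23.5% of the tested genes, where chance gives 10%. Under scaling to equal totals the median gene lay at 0.25 (log2), and 646 were called higher and 134 lower. A fit on only these 2 groups called 111 higher and 7 lower. There 25 of 50 named genes lost their call, among them rpl13a, rpl13, ar, mitfa, xdh, atic, foxd3, and1, and2, elavl4, ckmb, hspa8, hsp90ab1 and rxrba. The count was 243 without red 1, 171 without red 2, 370 without MZCS002 female 3 and 1166 without MZCS002 female 2. Of 50 named genes called here, 25 kept their call with every library left out in turn.

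Yellow tails also carried more pigment cell transcripts than tails of GRZ-BELL females. The iridophore gene fhl2a was at 3533 ± 2134 against 5.24 ± 7.67 (log2 change 9.75 ± 0.76), and apoda.1 at 7669 ± 2017 against 12.2 ± 15.2 (9.99 ± 0.78). Levels of tyr were 1685 ± 820 against 43.2 ± 21.9 (5.30 ± 0.44) and levels of csf1ra 2607 ± 793 against 304 ± 94.6 (3.09 ± 0.34). The pteridine genes aox6, an aldehyde oxidase, and pts, which makes a precursor of pteridines, rose by 4.77 ± 0.55 and 2.89 ± 0.28. The gene gch2 was at 12889 ± 12178 against 379 ± 586 (6.30 ± 1.08). The limma adjusted p was 2.7e-05 for fhl2a and apoda.1, 4.1e-05 for tyr, 2.7e-04 for csf1ra, 3.8e-04 for aox6, 1.2e-04 for pts and 0.0072 for gch2. The 3 yellow libraries lay above the 3 female ones for each. The call of gch2 was lost with edgeR.

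Of 19 melanin and melanosome genes, 8 rose in yellow tails and 1 fell (12 and 1 adjusted over the list alone). The risers included trpm1b (3.75 ± 0.28), mlana (2.60 ± 0.31), tyrp1b (2.68 ± 0.37) and pmela, whose product builds melanosome fibrils (2.58 ± 0.40). The gene that fell was slc7a11, a cystine transporter (-3.40 ± 0.76, limma adjusted p = 0.040). That call was lost without yellow 1, 2 or 3 and without GRZ-BELL female 1 or 3, with a highest limma adjusted p of 0.21. Of 19 guanine and iridophore genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone): pnp4a (from 5.41 ± 2.52 to 556 ± 271 normalized reads), pnp5a (4.15 ± 0.58), tfec (3.25 ± 0.32), fhl2a and alx4a (2.86 ± 0.50) rose, and the endothelin receptor gene ednrbb fell (-4.01 ± 0.81). The calls of alx4a (without yellow 2) and ednrbb (without yellow 1, yellow 2, GRZ-BELL female 1 or 3) were lost, with highest limma adjusted p of 0.060 and 0.11. Of 14 pteridine and xanthophore genes, 5 rose (6 adjusted over the list alone): csf1ra, aox6, pts, gch2 and pax7a, a transcription factor gene of the xanthophore lineage (3.23 ± 0.33). Camera gave adjusted p = 4.5e-17 for the melanin list, 3.7e-08 for the guanine list and 1.2e-04 for the pteridine list. With an estimated correlation the adjusted p was 0.26, 0.36 and 0.26.

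The gene vtna, which encodes the matrix protein vitronectin, rose from 12.4 ± 0.61 in GRZ-BELL females to 4076 ± 3247 in yellow tails (log2 change 7.97 ± 0.46, limma adjusted p = 4.4e-06). The tachykinin gene tac3a had no read in GRZ-BELL females and 204 ± 109 normalized reads in yellow tails, at least 73.3-fold higher. The nuclear receptor gene esrrga was at 646 ± 109 against 4.22 ± 2.47. Also higher were si:dkey-251i10.2 (8.14 ± 0.65), gpnmb (8.07 ± 0.58) and the heat shock gene hsp90aa1.2 (2.70 ± 0.33). The transcription factor gene foxq1a fell from a mean of 1357 to 105 normalized reads (-3.70 ± 0.53), and the cell cycle inhibitor gene cdkn1d from 4502 ± 1008 to 372 ± 194 (-3.69 ± 0.62). Of 11 blood genes, 2 rose (3 adjusted over the list alone): slc4a1a, the anion exchanger of red blood cells (2.51 ± 0.52), and tfr1a (1.52 ± 0.30). Camera gave the blood list adjusted p = 1.1e-04, and adjusted p = 0.44 with an estimated correlation. Its median per library was 2.30, 0.37 and 1.38 in yellow tails and -0.33 to 0.22 in GRZ-BELL females. The calls of slc4a1a and tfr1a were lost without yellow 1, GRZ-BELL female 1 or GRZ-BELL female 2, and also without yellow 3 for slc4a1a and yellow 2 for tfr1a. Their highest limma adjusted p was 0.15 and 0.11. Of 13 carotenoid genes, plin6 (3.90 ± 0.69) and the carotenoid-splitting enzyme gene bco1 (2.15 ± 0.49) rose and lpla fell (-1.53 ± 0.35). The call of bco1 was lost without any 1 of the 6 libraries compared, with a highest limma adjusted p of 0.22. That of plin6 was lost without yellow 2 (limma adjusted p = 0.063), and that of lpla without yellow 1, 2 or 3 or GRZ-BELL female 2 or 3 (highest 0.21).

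In all, limma called 279 genes at a Benjamini-Hochberg adjusted p under 0.05, 226 higher and 53 lower in yellow tails. All 279 had groups that did not overlap, as had 25.9% of the tested genes, where chance gives 10%. The count was 163 without yellow 1, 152 without yellow 2, and 178, 177 and 184 without GRZ-BELL females 1, 2 and 3. In a fit without MZCS002 female 2, which lies in neither group but enters the shared spread, it was 532. Of 42 named genes called here, 28 kept their call with every library left out in turn.

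**Figure D1:**
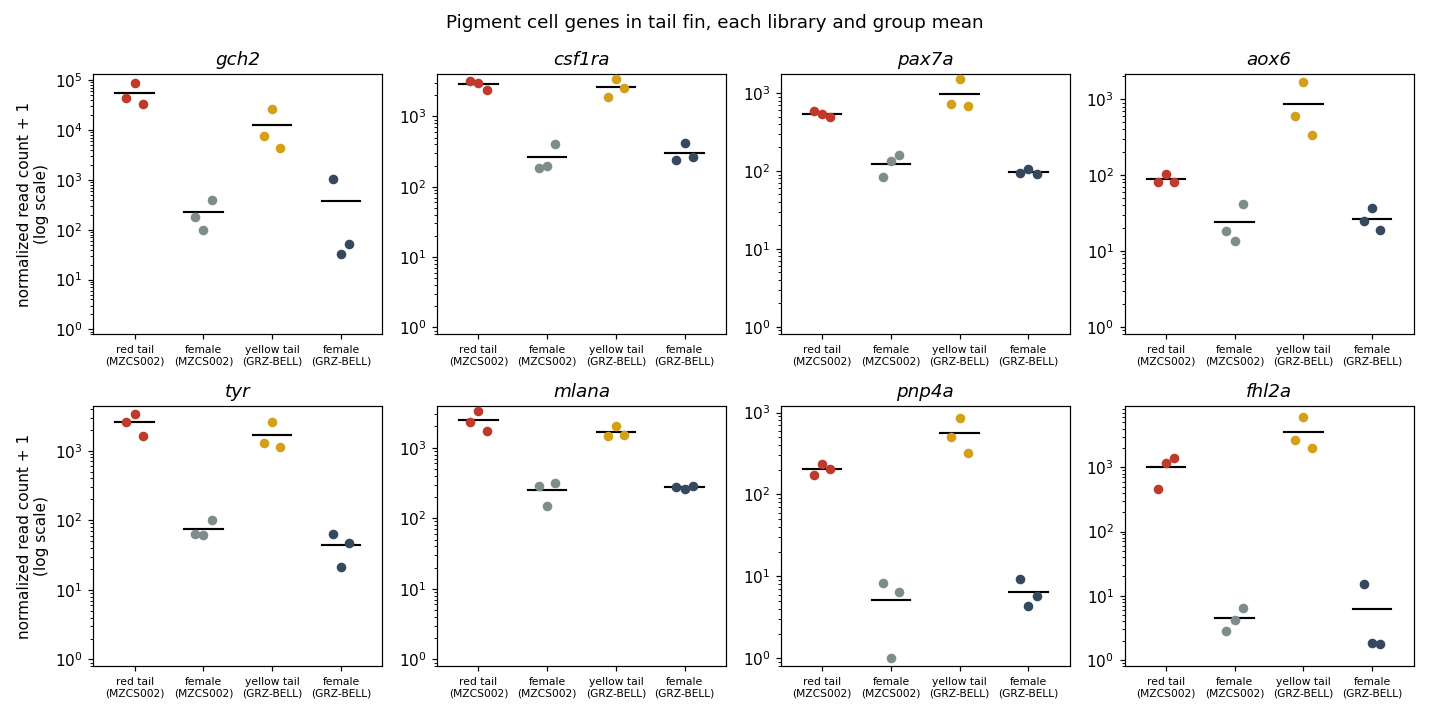
Normalized read counts plus 1 (log scale) of 8 pigment cell genes, with a point per library and a line at each group mean. In each of the 8 genes all 6 libraries of coloured tails lie above all 6 female libraries, and the yellow tails' mean of aox6 (876) lies above that of the red tails (88.1).

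Coloured tails of the strains shared more called genes than independent lists would. Both comparisons called 119 genes in the same direction, 114 higher and 5 lower, where independent lists would share 6.1 and 0.96, and 1 gene was called in opposite directions. Shared lower genes numbered 0 to 10 with a library left out. The comparisons share no library, but all 12 libraries entered the same fit, so both used the same spread per gene. Genes of small spread are called more readily in both, so the counts for independent lists are only a rough guide. Both comparisons also set coloured tails against females, so the sharing does not tell colour from sex. From the 4 pigment lists limma called tyr, mlana, trpm1b, tyrp1b, rab38b, tspan10, pnp4a, pnp5a, fhl2a, tfec, csf1ra, gch2, pax7a and plin6 higher and lpla lower in both. Across genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.30 and Spearman rho = 0.12. With a library left out the rho ran from 0.020 (without yellow 2) to 0.21 (without red 1).

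**Figure D2:**
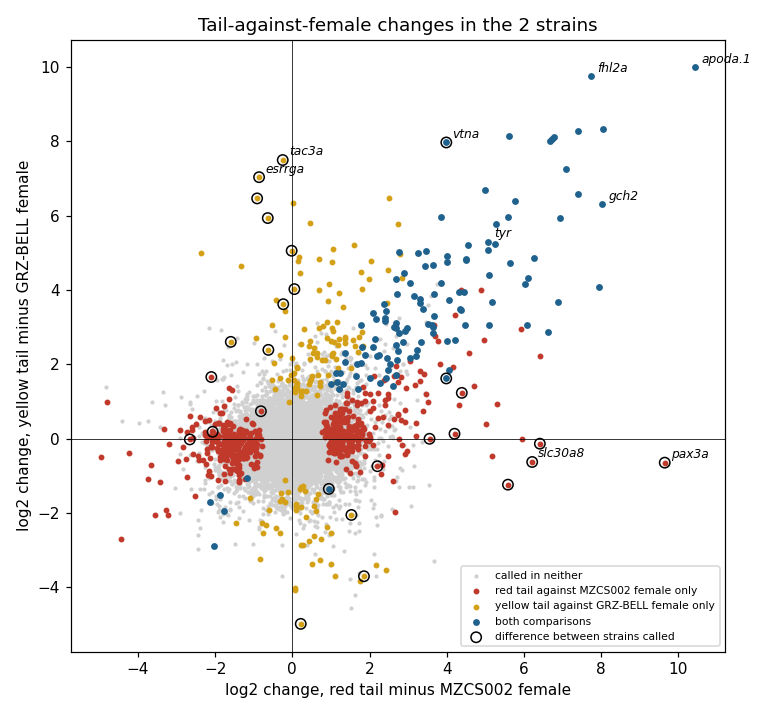
Log2 change of each of 15170 tested genes in red tails against MZCS002 females (horizontal) and in yellow tails against GRZ-BELL females (vertical), coloured by where limma called the gene, with rings around the 27 genes called for a difference between strains. Called genes such as apoda.1 (10.44 and 9.99) lie at the upper right, and pax3a (9.65) at the far right near the horizontal axis.

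For 27 genes limma called the tail-against-female difference itself as differing between strains. In simulation the interaction test recovered 0% of 2-fold and 21.2% of 4-fold changes, so genes not called can differ too. The gene pax3a, a neural crest and xanthophore transcription factor, was at 958 ± 69.2 in red tails but 0.92 ± 1.59 in yellow ones, and at 0.23 ± 0.39 and 2.61 ± 3.86 in the females. The zinc transporter genes slc30a8 (1185 ± 654 in red, 28.5 ± 16.3 in yellow tails) and slc39a6 (1870 ± 553 against 166 ± 43.9) also had their highest mean in red tails. So had il34, which encodes a ligand of the Csf1 receptor (826 ± 93.4 against 65.4 ± 15.3). The highest mean was in yellow tails for esrrga (646 ± 109 in yellow, 0.27 ± 0.46 in red tails), tac3a (204 ± 109, no read in red tails) and the microtubule-binding gene map7a (267 ± 20.2 against 51.5 ± 1.81). The interaction was 6.84 ± 0.85 for slc30a8, 3.56 ± 0.45 for slc39a6, 4.07 ± 0.60 for il34 and -3.97 ± 0.41 for map7a (log2, limma adjusted p 0.0084, 0.0091, 0.022 and 0.0048). The call of il34 was lost without red 1, red 2, any yellow library, or GRZ-BELL female 1 or 2, with a highest limma adjusted p of 0.090. That of tac3a was lost without yellow 2 or yellow 3 (highest 0.096).

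In all, limma called 27 genes for the interaction at a Benjamini-Hochberg adjusted p under 0.05, 13 higher and 14 lower in MZCS002, while 2193 had an unadjusted p under 0.05. None of the 65 tested members of the 4 pigment lists (melanin, pteridine, guanine and carotenoid) was among them (15 at an unadjusted p under 0.05, smallest limma adjusted p 0.066), though pax3a of the neural crest and pigment progenitor list was. By other tools, edgeR called 1 of the 65 and DESeq2 8. Without MZCS002 female 2 there were 3: slc7a11, tdh and oca2, named here after their values were seen. Among lists, camera called the ribosomal proteins (adjusted p = 2.8e-18, adjusted p = 0.72 with an estimated correlation, median -1.55, and -0.89 under quantile normalization) and blood (0.048, adjusted p = 0.77 with an estimated correlation). In limma 0 of 73 ribosomal members were called (25 lower adjusted over the list alone, 43 at an unadjusted p under 0.05), against 0 in edgeR and 21 in DESeq2. Of 11 blood members 0 were called (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), and 0 in edgeR and DESeq2. Without MZCS002 female 2 the blood list's adjusted p was 0.10. The count of 27 became 12 and 7 without red 1 and 2, 64 without red 3, and 55, 134 and 15 without MZCS002 females 1, 2 and 3. It became 7, 11 and 9 without yellow 1, 2 and 3, and 10, 9 and 10 without GRZ-BELL females 1, 2 and 3. Under equal totals, with the median gene at 0.32 (log2), 28 were higher and 7 lower.

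**Figure D3:**
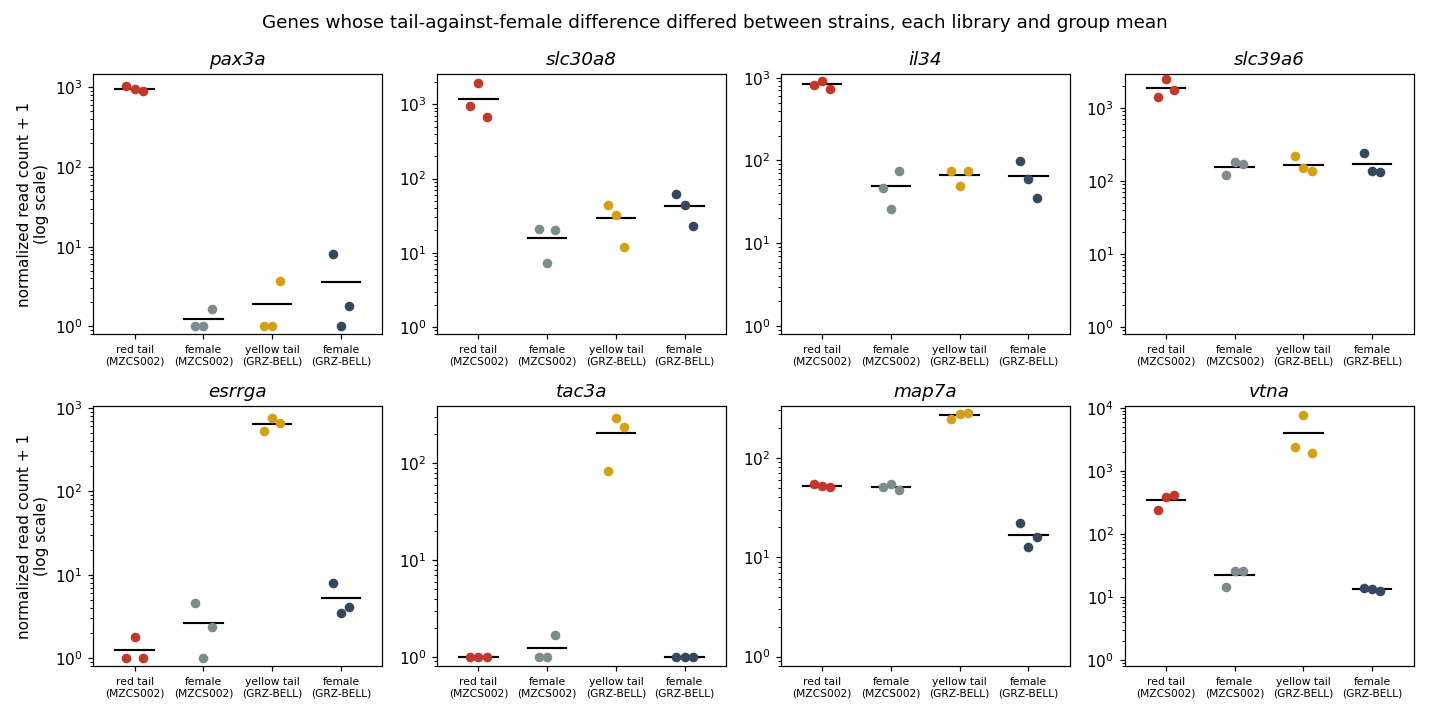
Normalized read counts plus 1 (log scale) of 8 genes called for a difference between strains, with a point per library and a line at each group mean. The upper panels show genes high in red tails (pax3a mean 958) and the lower panels genes highest in yellow tails (esrrga mean 646).

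Between red and yellow tails, which also differ in strain, several pigment genes were not called and others were. In simulation 5.88% of 2-fold changes were recovered for this contrast, so a missing call does not show equal levels. Levels of csf1ra (2845 ± 424 and 2607 ± 793) and tyr (2551 ± 871 and 1685 ± 820) differed by log2 0.16 ± 0.34 and 0.64 ± 0.44 and were not called (limma adjusted p 0.81 and 0.40). The mean of gch2 was 54884 ± 29798 in red and 12889 ± 12178 in yellow tails, a difference of 2.39 ± 1.08 that was not called either (limma adjusted p = 0.19). A fit on only the groups compared did call gch2. Also not called were xdh, mitfa, mitfb, dct, pmela and pnp4a (limma adjusted p 0.071 to 0.24). Each of these was called in a fit without MZCS002 female 2, chosen after the data were seen. DESeq2 called all of them but pmela, and edgeR called pnp4a. The red libraries of pnp4a (173 to 232) lay below the yellow ones (320 to 852). The genes csf1ra, tyr, gch2 and pax7a stayed uncalled with each library left out in turn. The pteridine genes aox6 and pts were lower in red tails, by log2 changes of -2.99 ± 0.55 and -1.23 ± 0.28. Higher in red tails were pax3a (2 reads in yellow tails, ratio 1045, 95% counting interval 380 to 11339), slc30a8 (5.39 ± 0.60) and asmt, which encodes the last enzyme of melatonin synthesis (at least 18.9-fold). Lower were tac3a (at least 84.5-fold), esrrga (1 read in red tails, ratio 2412, 435 to 95986) and the sulfate transporter gene slc13a1 (at least 30.5-fold). In limma, the adjusted p was 0.0074 for aox6, 0.022 for pts, 8.6e-05 for pax3a, 3.3e-04 for slc30a8, 8.4e-04 for asmt, 1.9e-04 for tac3a, 2.3e-05 for esrrga and 5.1e-05 for slc13a1. The call of pts was lost without red 1, red 3, yellow 2 or yellow 3 (highest limma adjusted p 0.097).

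By list, 3 of 19 melanin genes were higher in red tails (tspan36, tspan10 and rab32a; 5 higher and 4 lower adjusted over the list alone), 2 of 14 pteridine genes were lower, and 1 of 19 guanine genes was higher and 1 lower. None of these lists was called (camera adjusted p 0.71, 0.67 and 0.73), and 0 of 13 carotenoid genes passed in limma (3 at an unadjusted p under 0.05), against 1 in edgeR and 1 in DESeq2. The calls of tspan36, tspan10, rab32a and ltk were lost without red 1, red 2, yellow 1 or yellow 3, and that of ednrbb without red 1 or yellow 1. Those of tspan10 and ltk were also lost without red 3, and those of tspan36 and ltk without yellow 2. The highest limma adjusted p among these genes was 0.17. Cell cycle genes were higher in red tails: 10 of 23 were called (15 adjusted over the list alone), all 23 changes were positive, and the median was 2.11. The kinase gene cdk1 was at 1143 ± 368 against 130 ± 105. Between red tails and MZCS002 females 0 of 23 cell cycle genes were called, with a median of 0.012 (camera adjusted p = 0.99). Between females of the strains, all 23 changes were also positive, toward MZCS002. Fin matrix genes mgp (3.76 ± 0.52) and and2, of the actinotrichia (3.66 ± 0.64), were higher in red than in yellow tails. Of 11 blood genes, slc4a1a (-3.14 ± 0.52), tal1 and gata1a were lower (7 lower and 1 higher adjusted over the list alone). The 73 ribosomal protein genes had a median of -0.76 (0 called adjusted over the list alone), and rpl13a was lower. Its call was lost without red 1, red 2 or any yellow library (highest limma adjusted p 0.16). Camera gave adjusted p = 5.5e-08 for cell cycle, 6.0e-04 for blood and 5.8e-08 for ribosomal proteins. With an estimated correlation the adjusted p was 0.72, 0.48 and 0.89. The calls of tal1 and gata1a were lost without red 2, red 3, yellow 1 or yellow 3, and that of gata1a also without red 1 (highest limma adjusted p 0.16 each).

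In all, limma called 1127 genes at a Benjamini-Hochberg adjusted p under 0.05, 584 higher and 543 lower in red tails. Of these, 1126 had groups that did not overlap, as had 34.1% of the tested genes (chance gives 10%). Among entries with only an identifier, XM_015970483 was at least 341-fold higher in red tails, and XM_015946284 fell by 7.94 on the log2 scale. The count was 382 without red 1, 383 without red 2, 342 without yellow 1 and 580 without yellow 3, and 2616 in a fit without MZCS002 female 2. Scaling to equal totals gave 670 higher and 363 lower. Of 45 named genes called, 21 kept their call with every library left out in turn.

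Females of the strains differed in genes of varied function. Higher in MZCS002 females were mycbpap (83.4 ± 13.7 against 1.19 ± 0.37, log2 change 5.27 ± 0.53), tegt (877 ± 290 against 79.9 ± 20.4, 3.42 ± 0.31), pnkd (4.76 ± 0.58), the phospholipid carrier gene pctp (3.94 ± 0.44) and the cartilage collagen gene col9a1b (at least 25.5-fold). Lower were slc13a1 (at least 22.0-fold), abcc8, which encodes a subunit of potassium channels (at least 11.8-fold), the muscle calcium channel gene ryr1b (9.36 ± 15.4 against 333 ± 26.5, -6.47 ± 0.98) and gpat2 (-4.86 ± 0.69). The limma adjusted p was 2.1e-04 for mycbpap, 1.1e-04 for tegt, 2.8e-05 for slc13a1, 3.5e-04 for abcc8 and 0.0043 for ryr1b. Of the pigment genes, slc7a11 was lower (-4.70 ± 0.76), the only limma call among the 65 tested members of the 4 pigment lists, while DESeq2 also called 1 of 19 guanine genes. Cell cycle genes leaned higher in MZCS002 females, with all 23 changes positive and a median of 1.28, but cdc20 was the only 1 called by limma (4 adjusted over the list alone), against 2 in edgeR and 6 in DESeq2. Without MZCS002 female 2, which had the highest cell cycle level of the 12 libraries, the median was 0.86. Ribosomal protein genes had a median of 0.63 with 0 of 73 called in limma (0 adjusted over the list alone, 12 at an unadjusted p under 0.05), 0 in edgeR and 1 in DESeq2. Their median was 0.31 without MZCS002 female 2 (camera adjusted p = 0.0063) and 0.19 under quantile normalization. Camera gave adjusted p = 1.3e-08 and 2.9e-08 for these lists, and adjusted p = 0.72 and 0.89 with an estimated correlation. The call of cdc20 was lost without MZCS002 female 2 or 3 and without any GRZ-BELL female (highest limma adjusted p 0.15).

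In all, limma called 264 genes at a Benjamini-Hochberg adjusted p under 0.05, 124 higher and 140 lower in MZCS002 females, all with groups that did not overlap, as had 20.1% of the tested genes (chance gives 10%). A fit on only these 2 groups called 34 higher and 39 lower, and 9 of 22 named genes lost their call there, among them ryr1b, gpat2, col9a1b, slc7a11, cdc20 and agr2. The count was 111, 112 and 133 without GRZ-BELL females 1, 2 and 3. Under scaling to equal totals the median gene lay at -0.23 (log2), and 85 were called higher and 178 lower. Of the 264 genes, 160 were also called between red and yellow tails in the same direction, 78 higher and 82 lower, where independent lists would share 4.8 and 5.0, and 2 were opposite. These included slc13a1, unc13a, ryr1b and mycbpap. Both strain comparisons used the same spread per gene, so the counts for independent lists are only a rough guide. The overlap was 98 without yellow 1, and 87, 87 and 96 without GRZ-BELL females 1, 2 and 3. Across genes the log2 changes correlated at Pearson r = 0.44 and Spearman rho = 0.26 (0.18 to 0.33 with a library left out).

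The other lists gave no camera call at adjusted p under 0.05 in any of the 5 contrasts: carotenoid handling, neural crest and pigment progenitor, sex steroid, thyroid hormone, fin matrix, epidermis, muscle, immune cells, interferon response, nerve and glia, vessel, and immediate early and heat shock genes. Members of these lists were called singly. Between red and yellow tails, pax3a and ednrbb (neural crest), mgp, and2 and msx1a (fin matrix), srd5a3 (sex steroid), mmp13b (immune cells) and dusp2 (immediate early) were higher in red tails. There rxrba (thyroid hormone), ryr1b (muscle), cspg4 (vessel) and hsp90ab1 (heat shock) were lower. All of these calls except those of pax3a, mgp and and2 were lost without red 1, many of them without other libraries too, and their highest limma adjusted p ran from 0.053 to 0.14. Against MZCS002 females, pax3a, mitfa and foxd3, and1 and and2, ar and dusp2 were higher in red tails, and rxrba, elavl4 (nerve), ckmb (muscle), hspa8 and hsp90ab1 were lower. All of these calls but those of pax3a and dusp2 were lost without red 1, and all but mitfa of the lost ones also without MZCS002 female 3, with a highest limma adjusted p of 0.18. Against GRZ-BELL females, foxd3, mitfb and hsp90aa1.2 were higher in yellow tails, and ednrbb and mgp were lower. All but hsp90aa1.2 lost their call without yellow 1, with a highest limma adjusted p of 0.19. Between females, agr2 of the epidermis list was higher and ryr1b lower in MZCS002. The call of agr2 was lost without MZCS002 female 1 or 3 and without any GRZ-BELL female (highest limma adjusted p 0.16). For the interaction, pax3a was called. Of 7 interferon response genes, 0 were called in any contrast in limma (1 at an unadjusted p under 0.05, in red tails against females), and 0 in edgeR and DESeq2. Median and mean differed in sign for neural crest genes between red and yellow tails (-0.42 and 0.63), and for carotenoid genes (0.15 and -0.29). The medians of all 15 called pairs of list and contrast kept their sign under quantile normalization and under equal totals.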

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

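The tests of possible causes for the 27 interaction genes, those of the ribosomal protein genes without MZCS002 female 2 and by permutation, and the readings of the splits were chosen only after the result was seen, while the interaction test was planned, and the test against matched lists and the permutation of residuals were set before their results.

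The difference between tail and female differed between strains, by the interaction test, for 16 named genes. A positive log2 value means a larger difference in MZCS002. It was 10.30 for pax3a, 6.84 for slc30a8, 6.55 for the potassium channel gene kcnk3a, 5.56 for foxq1a, 4.07 for il34, 3.58 for the melanocortin receptor gene mc5ra, 3.56 for slc39a6 and 2.37 for mreg (melanoregulin). It was -3.85 for armh4, -3.97 for map7a, -3.98 for vtna, -4.20 for trpc4a, -6.57 for onecut2, -7.38 for lhx6b, -7.75 for tac3a and -7.90 for esrrga. The values of pax3a, onecut2, lhx6b, tac3a and esrrga depend on the pseudocount, because groups lay at or near 0 reads. With each library left out in turn, pax3a, slc30a8, slc39a6, map7a and esrrga kept their call, and foxq1a lost it only without red 2 (limma adjusted p = 0.051). The call of mreg was lost without red 2 or 3 or any GRZ-BELL library, and that of mc5ra without any library but MZCS002 females 2 and 3, both with a highest limma adjusted p of 0.15. The calls of kcnk3a, armh4, vtna, trpc4a, onecut2 and lhx6b were lost without red 1, yellow 1 or any GRZ-BELL female, among others (highest limma adjusted p 0.17).

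All 27 genes called for this difference were called in the same direction without the low-depth library MZCS002 female 2, so these calls did not depend on it. Without that library 134 genes were called in all. Calls were thus easier to keep there, which makes this a weak test of that library as the cause. If all reads of a gene were lost in 1 strain, as with a sequence that differs from the reference, tail and female would both lie near 0 there. For 21 genes reads were present in both strains: the higher group mean of each strain was at least 17.8 (kcnk3a, SD 2.93). There 3 reads per library came to at most 4.72. These genes were set apart by a group mean of at least 5 in each strain, so passing that floor was fixed by the choice. It describes genes that had not lost all reads in a strain and is no test. For the other 6 it stays open, because both means of a strain were under 5: pax3a, esrrga, tac3a, lhx6b, onecut2 and XM_015943237. Swings between libraries of genes that move together would call genes without an interaction: when residuals were permuted between libraries, 1 of 100 permutations called at least 27 genes (195, the next 10), which argues against them at 0.05. A partial loss was not tested. Colour, strain and sex, which the design joins, also stay open as untested explanations.

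Ribosomal protein genes were lower in red tails than in MZCS002 females, with a median log2 change of -1.54 (bootstrap SE over genes 0.082, which leaves out the spread between libraries) and -0.91 under quantile normalization. In a fit on only these 2 groups limma called 0 of the 73 genes (54 at an unadjusted p under 0.05), against 29 in edgeR and 56 in DESeq2 fitted on all groups. Without MZCS002 female 2 the median was -1.19, and without red 1 as well -0.88, and the 3 red libraries stayed below the females other than MZCS002 female 2, which argues against that library as the whole cause. A loss of abundant transcripts in general was set against 10000 lists of other genes matched on mean expression. Their median was -0.22 and their lowest value -0.63, against -1.54 for the ribosomal genes. These values argue against such a loss as the whole cause. As a part of the cause it stays open: 91.9% of the lists lay above the bound of -0.38, where 95% had been set as needed to exclude it. Swings between libraries of genes that move together stay open as well, because the exact two-sided permutation test of the 6 library medians gave p = 0.1, the smallest that 3 against 3 allows. A difference between red tails and females in the tissue itself was not tested apart from these.

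Other splits of the libraries were counted for each total. For red against yellow tail, 1 of 10 splits, the real one, called as many as 1127 genes, and the highest other called 0. The same count of 1 of 10 held for female against female (264, highest other 0), red tail against female (687, highest other 7) and yellow tail against female (279, highest other 0). With 10 splits no share under 0.05 is possible. For the interaction, 2 of 100 drawn splits called at least 27 genes. The other split called 151, which points to a structure of the samples: it kept yellow tails against GRZ-BELL females and set red 1 with MZCS002 females 1 and 3 against red 2, red 3 and female 2, so it still held the real difference in GRZ-BELL. With the tail-against-female difference common to the strains removed first, 1 of the same 100 splits, the real one, called as many as 27 (highest other 3). Of the 99 other splits 14 and 3 called any gene, because mixing tails with females widens the spread, so neither count tests chance. For the 119 genes shared by the tail-against-female comparisons 1 of 100 splits, the real one, reached the count (highest other 0), and for the 160 genes shared by the strain comparisons also 1 of 100 (highest other 2). Of the 99 other splits, 3 and 1 called any gene in both comparisons, so these counts do not test whether the sharing was by chance.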

How the results depend on the processing

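The fits without MZCS002 female 2 of comparisons that do not include it, and of the gene lists, were chosen only after the data were seen. The other alternatives were planned. Counts of called genes kept within 1.5 times under alternatives not named here, and no single value turned its direction in 4057 alternatives: 3504 kept their side of the threshold, 521 lost a call and 32 gained one. A fit on only the groups compared gave 1767 genes for red against yellow tail, 73 for female against female, 118 for red tail against female and 591 for yellow tail against female. DESeq2 gave 2350, 808, 1757 and 7.1e+02, and 625 for the interaction. A mean of at least 50 gave 145 between females, 13 for the interaction and 86 shared by the strain comparisons, with fewer genes tested. For the interaction a pseudocount of 0.5 gave 16 and of 8 gave 61. Apart from fewer genes or samples, the cause was not tested.

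With each library left out in turn, red against yellow tail gave 342 (without yellow 1) to 1150 genes, and 2616 without MZCS002 female 2. Female against female gave 111 (without GRZ-BELL female 1) to 358 (without MZCS002 female 2). Red tail against female gave 171 (without red 2) to 1166 (without MZCS002 female 2), and yellow tail against female 152 (without yellow 2) to 220, and 532 without MZCS002 female 2. The interaction gave 7 (without red 2 or yellow 1) to 134 (without MZCS002 female 2). The tail-against-female overlap ran from 81 to 160 and the strain overlap from 87 (without GRZ-BELL female 1 or 2) to 226. Interaction calls within the pigment lists ran from 0 to 3 (without MZCS002 female 2). They numbered 1 under equal totals, 1 with edgeR and 8 with DESeq2. Of 15 list calls, 0 remained with an estimated correlation. The test fry made 8 list calls, 7 of them among the 15, and added neural crest genes in red tails against females. The 7 were the melanin, guanine and pteridine lists in each tail against females, and blood between red and yellow tails. All ribosomal protein and cell cycle calls, and the other blood calls, were lost with fry. Without MZCS002 female 2 camera made 14 list calls, 13 of them among the 15, with cell cycle genes added for the interaction. Under quantile normalization camera made 16, the 15 and neural crest genes in yellow tails against GRZ-BELL females (adjusted p = 0.043).

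The labels do not say whether libraries with the same replicate number share anything else, and their values gave little sign of it. Of 18 such pairs 3 had deviations correlated above 0.1 (-0.31 to 0.17), and 2 of 12 libraries correlated best with their own number. Shared handling was not excluded by this. With the number as a block, the calls were 835 for red against yellow tail, 210 for female against female, 347 for red tail against female, 240 for yellow tail against female and 14 for the interaction. The block gave 16 list calls, the 15 and immediate early and heat shock genes between females, and overlaps of 98 and 136. Small changes were mostly missed: in simulation 0% (interaction) to 5.88% (red against yellow tail) of genes with a planted change of 2-fold were recovered.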

Other observations

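All tests in this part were chosen only after the result was seen, and their lists of genes were formed from symbols.

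Proteasome genes, whose products break down proteins, leaned higher in red tails. Of 41 genes with proteasome symbols, which also took in psmc3ip, a recombination gene, and the assembly chaperones psmg1, psmg3 and psmg4, 11 rose against yellow tails (among them psmc2, psmc6, psma2a and psmb1; median log2 change 0.86) and 5 against MZCS002 females (psmc2, psmc4, psmb1, psmd13 and psmg4; median 0.79). Camera, adjusted over 25 pairs of list and contrast, gave adjusted p = 2.8e-09 and 2.1e-08, and adjusted p = 0.28 for both with an estimated correlation. For the interaction the median was 0.90, with camera adjusted p = 2.1e-08 and adjusted p = 0.28 with an estimated correlation. Vacuolar ATPase genes, which acidify organelles, were higher in red tails than in MZCS002 females: 5 of 17 rose (atp6v1c1a, atp6v0e1, atp6v0d1, atp6v1h and atp6ap2), all 17 changes were positive, and the median was 0.61. The list had a camera adjusted p of 3.0e-05, and adjusted p = 0.28 with an estimated correlation. Camera also called it higher in yellow tails than in GRZ-BELL females (13 of 17 changes positive, median 0.25, adjusted p = 0.016). It was called for red against yellow tails (0.023) and for the interaction (0.046) too. With an estimated correlation these adjusted p were 0.36, 0.39 and 0.43.

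Sterol synthesis genes leaned higher in red than in yellow tails and lower in yellow tails than in GRZ-BELL females, with few members called. Of 17, nsdhl, acat2, fdps, ebp and lss were higher in red than in yellow tails (median log2 change 1.41). In yellow tails acat2 and lss were lower than in GRZ-BELL females (median -0.71). By camera the adjusted p was 1.0e-06 and 1.5e-05, and 3.0e-05 for the interaction, where acat2 was called. The adjusted p was 0.28 for all of these with an estimated correlation. Of 13 zinc transporter genes, slc39a6 and slc30a8 rose in red tails against MZCS002 females (camera adjusted p = 0.010, adjusted p = 0.28 with an estimated correlation). Between red and yellow tails 2 were higher and 2 lower (camera adjusted p = 0.40), and the interaction had a camera adjusted p of 0.087.

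Of 61 mitochondrial ribosomal protein genes, 52 changes were positive in yellow tails against GRZ-BELL females (median 0.26). The camera test gave adjusted p = 0.0020, and adjusted p = 0.70 with an estimated correlation. Camera also called the list higher in red tails against MZCS002 females (adjusted p = 0.021) and against yellow tails (0.029). It was called higher in MZCS002 than in GRZ-BELL females too (0.0056), where its median was 0.32, and 0.0055 without MZCS002 female 2. In red tails against MZCS002 females the median of the mitochondrial genes was 0.21 (0.44 without MZCS002 female 2) and that of the cytosolic ribosomal genes -1.54. None of these calls held with an estimated correlation. Under quantile normalization the medians were 0.18 and -0.91.

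Some genes had at most 3 reads in all 6 libraries of 1 strain and a value of at least 10 in each library of the other. Of these, 8 were near 0 in MZCS002, among them slc13a1, unc13a (a synaptic vesicle gene), abcc8 and slc17a6a (a glutamate transporter gene), and 5 were near 0 in GRZ-BELL, none with a symbol. The split of 8 against 5 did not differ from an even one (exact two-sided binomial p = 0.58).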
